A study of Oryza sativa with 12 samples.

How the data were processed

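The series holds 12 Agilent rice arrays of 60-mer probes, each hybridised with a pair of RNA samples. Per the labels, total RNA came from the shoot base of wild-type (WT) and rss1-2 seedlings kept for 7 days on MS medium with 0 or 150 mM NaCl. Each of the 4 groups (WT control, WT salt, rss1 control, rss1 salt) has 3 biological replicates per the series design. Per the labels, the sample named for the group carried Cy3 and the reference on every array was Cy5-labelled unstressed WT RNA of the same replicate number. The 3 WT control arrays therefore hold the same RNA in both channels, so their spread has no biological part. No array has the dyes exchanged. Each slide holds the 4 arrays of one replicate number, so a replicate number and a slide are the same thing here.

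Per the file headers, the scanner files were made with Agilent Feature Extraction 9.5.3.1. They give mean spot signals and median local backgrounds as raw intensity, and processed signals as intensity after background subtraction, spatial detrending and dye normalization with linear and LOWESS factors, per the file headers. The log ratio column is log10 of the red over the green processed signal per the file headers. Where Cy3 alone is used below, it is the processed Cy3 signal, which is already dye-normalized. The deposited values of the series matrix are in natural log (ln) of Cy3 over Cy5, a scale and direction read from bright spots, and their column medians lie between -0.0016 and 0.0554. The normalization behind them is not given in the sources used here, and weak spots are compressed in them.

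Each array has 45151 spots and 42423 probes were used. The main values start from the raw mean signals and local backgrounds. Spots that the scanner software called outliers were set missing. So were 6 spots on 2 arrays, 5 on rss1 salt replicate 1 and 1 on rss1 salt replicate 3, with a local background over 10 times the median of their array. This step was chosen after seeing the data, and the result with those spots kept is an added alternative. Background was corrected with normexp (offset 50), and the ratio was normalized within each array by loess in limma 3.58.1 under R 4.3.3 with the data.table package (1.17.8) and statmod 1.5.0. No scaling between arrays was applied, and ratios are Cy3 over Cy5 in log2. A probe was kept if its Cy3 signal was well above background on all 3 arrays of at least 1 group, which left 35221 probes. The kept probe with the highest mean signal stood for its gene. This gave 24295 genes, 24139 named by locus and 155 of them microRNA precursor probes.

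One limma model with a mean per group and moderated variances gave 5 comparisons: WT salt minus WT control, rss1 control minus WT control, rss1 salt minus WT salt, rss1 salt minus rss1 control, and the difference of the salt changes, rss1 minus WT, called the interaction here. Since the common reference cancels, each comparison is a difference between groups of ratios. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene passed at an adjusted p under 0.05. They measure the spread between these samples. The variance of each gene was pooled over all groups, including the self-hybridised WT control arrays, whose spread has no biological part. This pooling can lower the SEs and p-values of every comparison, including those in which the WT control arrays are not compared. Changes are printed in log2 ± SE from this model with n = 3 arrays per group. Where a probe was not well above background on any array of a group, a bound on the fold is given instead in comparisons of a pair of groups. No bound is formed for the interaction. It compares the brighter group's mean with the dimmer group's mean, taking on each dim array the higher of its lowest well-above-background signal and the probe's own signal, in the Cy3 channel after loess and Aquantile scaling, so dye bias stays open in these bounds.

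The design, the gene lists, the rule for the genes named in the text and the other settings were fixed before the data were examined. The rule named, per comparison, the 8 largest rises and 8 largest falls that passed, had the same sign on all 3 slides and had an informative description, plus up to 4 members of each list with the smallest p and a list of well-known salt and meristem genes. Gene names and descriptions are those of the array annotation. The 28 lists tested were the well-known salt and meristem genes (17 measured), DNA replication, core histones, mitosis, G1 control, cytosolic ribosomal proteins, photosynthesis, meristem and leaf primordium regulators, root and crown root markers, vascular and secondary wall genes, cuticle and epidermis genes, LEA proteins and dehydrins, the abscisic acid (ABA), jasmonate, cytokinin, auxin, gibberellin and ethylene pathways, expansins and wall loosening, ion transport, aquaporins, osmolyte synthesis, antioxidant enzymes, class III peroxidases, heat shock proteins, defence, the NAC, DREB and WRKY factors, and reference genes. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01 on the 24215 genes measured on all arrays, adjusted over 140 tests. Of these, 64 passed, and 0 passed with the correlation estimated from the data. Limma's fry, which asks whether the members of a list move one way on balance, passed 107. The transcript of RSS1 itself was not analysed here.

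Deviations of same-numbered arrays from their group means correlated across genes at 0.132 to 0.584 in the 9 pairs among WT salt, rss1 control and rss1 salt, and at -0.00319 to 0.0816 in the 9 pairs with a WT control array. Replicate numbers thus pair the arrays of the 3 groups that are not self-hybridised. With the replicate number as a block, 11968, 3277, 16549, 18288 and 12727 genes passed in the 5 comparisons, in the order above, against 10935, 2448, 15798, 17744 and 11652 without it.

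The alternatives were the scanner log ratio, the deposited values, no background subtraction, normexp offset 0, median centring in place of loess, Aquantile scaling between arrays, no filter on dim probes, a strict filter (31929 probes well above background in both channels on all arrays), every probe separately, the replicate block, the slide as a random block, Cy3 alone (one-colour, with and without the block), the ratio against 0 without the WT control arrays, only the arrays compared, eBayes with trend and robust, a minimum absolute log2 change of 1, the other list tests, and leaving out each replicate number and each array. Relative to loess, the median of all genes moved by -0.12, -0.12 and -0.16 with median centring in WT salt minus WT control, rss1 salt minus WT salt and rss1 salt minus rss1 control, and by -0.11 and -0.12 with the scanner log ratio in the latter pair.

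The pipeline was tested on simulated data with 200 planted changes among 24295 genes per comparison. It recovered 65.7, 67.2, 67.2, 64.2 and 38.8% of those planted at 0.5 in log2 in the 5 comparisons, and 85.1, 92.5, 91.0, 86.6 and 83.6% of those planted at 1. False calls numbered 12, 7, 8, 6 and 8. Of 50 unshifted lists 0 were called in any comparison, and a list of 40 genes shifted by 0.3 was found in all 5. The simulated genes varied independently of each other. These list results therefore do not show how the list test behaves when genes are correlated. Each simulated gene also had the same spread in all groups and no effect of the slide, and few genes were changed. The false calls therefore do not show how the gene test behaves with the unequal spreads and paired slides of the real arrays.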

Results

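Transcript abundance was measured in the shoot base, which holds the shoot meristem and young leaves, of rice (Oryza sativa) seedlings. They were wild type (WT) or carried rss1-2, a mutant allele of rice salt sensitive 1. RSS1 is known as a protein whose level changes through the cell cycle and which rice needs to keep its meristems active under salt. Each of the 4 groups, WT and rss1 with 0 or 150 mM NaCl for 7 days, has 3 arrays. The Cy3 signal was well above background for 33464 to 35744 of 42423 probes per array (78.9 to 84.3%), the median Cy3 signal was 438 to 609 against a background of 44.5 to 46.5, and 0 probes were saturated. The number of arrays limits the precision: the median SD of the log2 ratio over genes was 0.04 in WT control, 0.08 in WT salt, 0.10 in rss1 control and 0.12 in rss1 salt. The self-hybridised WT control arrays lack biological spread, yet they enter the pooled variance behind the SEs and p-values of every comparison. Every gene said by name to rise or fall passed the limma test and had the same sign on all 3 slides, while the counts within lists hold all genes that passed.

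The response of WT to salt was asked first, by comparing WT salt with WT control. Among the largest rises were those of a beta-glucosidase aggregating factor (Os12g0247700) by 5.59 ± 0.33 (adjusted p = 4.19e-06, WT control measured on 1 of 3 arrays) and arginine decarboxylase (Os04g0107600), which opens polyamine synthesis, by 4.46 ± 0.17 (7.44e-07). A pair of nicotianamine synthases, which make a chelator of iron and other metals, rose by 4.87 ± 0.85 (Os03g0307300) and 4.61 ± 0.58 (Os03g0307200), each measured on 1 of 3 WT control arrays. The plasma membrane aquaporin PIP2.3 (Os09g0541000), a water channel, rose by 3.37 ± 0.18 (2.53e-06), and catalase A (Os02g0115700), which breaks down hydrogen peroxide, by 3.28 ± 0.25. The copper transporter 1 gene (Os01g0770700) rose by 3.19 ± 0.22 (8.54e-06). The largest falls included a peroxidase (Os06g0546500) at -3.26 ± 0.27 and an ERF domain factor (Os09g0287000) at -2.50 ± 0.31.

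Lists of growth genes were lower on salt in WT. Of 155 cytosolic ribosomal proteins, 116 fell, 1 rose and 38 did not pass (129 down and 1 up adjusted over the list alone), with a median of -0.26. The camera test gave an adjusted p = 3.64e-16 and an adjusted p = 0.441 with an estimated correlation. L11 (Os02g0235600) fell by 0.56 on the log2 scale. Of 33 DNA replication genes 20 fell and 2 rose (23 and 2 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 1.76e-05, adjusted p = 0.450 with an estimated correlation), among them the replication factor C subunit Os12g0176500 at -0.57 ± 0.07. Core histones, the proteins that package DNA, fell in 19 of 47 cases and rose in 0 (19 and 0 adjusted over the list alone). The median was -0.34 (adjusted p = 4.21e-05, adjusted p = 0.545 with an estimated correlation). Of 65 mitosis genes 35 fell and 6 rose (37 and 6 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.00126, adjusted p = 0.560 with an estimated correlation), and the B-type cyclin Os06g0726800, which drives entry into mitosis, changed by -0.51 ± 0.07. Meristem and leaf primordium regulators fell in 17 of 38 cases and rose in 5 (18 and 5 adjusted over the list alone). Their median was -0.40 (adjusted p = 0.00697, adjusted p = 0.450 with an estimated correlation). That call ended with median centring (adjusted p = 0.0645; 0.000277 to 0.0645 over the alternatives). Its falls included growth-regulating factor 3 (Os03g0674700) at -1.30 ± 0.12 and the knotted1-type homeobox gene OSH43 (Os03g0771500) at -1.21 ± 0.13.

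Other lists were higher on salt in WT. Of 16 cuticle and epidermis genes 10 rose and 2 fell (10 and 2 adjusted over the list alone). The median was 0.71 (camera adjusted p = 0.00855, adjusted p = 0.188 with an estimated correlation). The lipid transfer protein LTP2P (Os06g0705400) rose by 2.51 ± 0.16. Ion transport genes rose in 31 of 68 cases and fell in 3 (33 and 3 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.000262, adjusted p = 0.188 with an estimated correlation), among them the vacuolar proton pyrophosphatase Ovp2 (Os06g0178900) by 0.88 ± 0.09. Of 34 jasmonate genes 17 rose and 5 fell (17 and 5 adjusted over the list alone), with a median of 0.32 (adjusted p = 0.0118, adjusted p = 0.454 with an estimated correlation), and a lipoxygenase (Os02g0194700), of the family that starts jasmonate synthesis, was at least 8.99-fold higher. Root and crown root markers rose in 5 of 14 cases and fell in 0 (5 and 0 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0255, adjusted p = 0.441 with an estimated correlation), among them RCc2 (Os04g0612500) by 1.74 ± 0.22. Of 81 expansins and wall-loosening genes 30 rose and 14 fell (31 and 14 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0289, adjusted p = 0.341 with an estimated correlation), a call that ended in the deposited values (adjusted p = 0.0507; 0.00465 to 0.0507 over the alternatives). Expansin EXPA21 (Os03g0377100) rose by 2.10 ± 0.09.

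Photosynthesis, vascular and antioxidant lists sat near the threshold in WT. Of 119 photosynthesis genes 38 rose and 12 fell, also adjusted over the list alone, with a median of 0.16 that became -0.03 with median centring (camera adjusted p = 0.0394, adjusted p = 0.612 with an estimated correlation). That call ended without WT salt replicate 1 (0.0515), WT salt replicate 2 (0.242), WT control replicate 2 (0.0822) and replicate 2 (0.331), with median centring (0.0868), in Cy3 alone (0.0564) and in the deposited values (0.207), with a range of 0.000135 to 0.331 over the alternatives. Of 44 vascular and secondary wall genes 18 rose and 6 fell, also adjusted over the list alone. Their median was 0.16 (adjusted p = 0.0396, adjusted p = 0.444 with an estimated correlation). Their call ended without WT salt replicate 3 (0.0554) and replicate 1 (0.0557), with the strict filter (0.0523) and in the deposited values (0.0641), with a range of 0.000266 to 0.0641. Of 94 antioxidant enzymes 37 rose and 16 fell, also adjusted over the list alone. The median was 0.14 (adjusted p = 0.0394, adjusted p = 0.454 with an estimated correlation). Here the call ended without WT control replicate 2 (0.0544), WT salt replicate 1 or 2 (0.0607 each), replicate 1 (0.0646) and replicate 2 (0.0685) and in the deposited values (0.0853), with a range of 0.00262 to 0.0853.

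Of the 17 well-known salt and meristem genes 6 rose and 1 fell in WT on salt, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.135), though it did with the scanner log ratio (0.0395) and median centring (0.0452; 0.0395 to 0.286 over the alternatives). The group 3 LEA protein Os05g0542500, of a family that protects drying cells, rose by 2.46 ± 0.32, the ABA-responsive element binding factor Os02g0766700 by 0.99 ± 0.06 and the dehydrin RAB16B (Os11g0454200) by 1.08 ± 0.11, the last with an adjusted p = 6.24e-05 that was 0.0531 with the outlying background spots kept (2.61e-05 to 0.0531 over the alternatives). The vacuolar sodium antiporter NHX1 (Os07g0666900) had -0.14 (adjusted p = 0.471) and the proline synthesis gene P5CS (Os05g0455500) -0.23 (0.0836), and neither passed. LEA proteins and dehydrins rose in 12 of 32 cases and fell in 2 (camera adjusted p = 0.18), ABA pathway genes in 14 of 66 and 10 (0.673), defence genes in 46 of 156 and 23 (0.188), and NAC, DREB and WRKY factors in 23 of 98 and 13 (0.477). Class III peroxidases rose in 30 of 96 cases and fell in 18 (0.271), and G1 control genes rose in 3 of 13 and fell in 6 (0.287). Over the alternatives LEA proteins and dehydrins ranged from 0.0302 to 0.373, passing with every probe separately, defence genes from 0.0218 to 0.245, passing with the scanner log ratio, median centring and Cy3 alone, and class III peroxidases from 0.0249 to 0.410, passing with median centring. The heat shock protein HSP101 (Os05g0519700), a disaggregase, rose by 2.36 ± 0.11 and heat shock factor 29 (Os06g0553100) by 2.28 ± 0.09.

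In all, 10935 of 24295 genes passed in WT on salt, 5453 up and 5482 down, 1077 of them by at least 1 in log2 (847 up and 230 down), and 10891 had the same sign on all 3 slides. The split was 4536 up and 7450 down with the scanner log ratio, 3262 and 8450 with median centring, 4641 and 7116 in Cy3 alone, and 4731 and 7446 in Cy3 alone with the replicate block. Without replicate 1, 5270 genes passed, and without replicate 2, 5702.

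The effect of the mutation without salt was asked by comparing rss1 control with WT control. Genes of small antimicrobial peptides were among the largest rises: thionin (Os06g0514100) by 4.47 ± 0.41 (adjusted p = 0.000178, WT control measured on 2 of 3 arrays) and a phoratoxin-type thionin (Os06g0514800) by 3.24 ± 0.43 (0.00181, on 1 of 3). A ubiquitin gene (Os09g0483400) rose by 2.80 ± 0.18 (1.89e-05), and the glutathione S-transferase TSI-1 (Os10g0527400), of a family that detoxifies reactive compounds, by 1.63 ± 0.16. Among the largest falls were those of an aldo/keto reductase (Os01g0847600) at -2.30 ± 0.09 (6.34e-07), an ACT domain protein (Os04g0391500) at -1.88 ± 0.13, the ribosomal protein L44 gene Os07g0523300 at -1.67 ± 0.06 (2.80e-07) and ABCE1 (Os10g0432200), a ribosome recycling factor, at -1.58 ± 0.13. The heat shock factors named were lower: HSF21 (Os03g0161900) at -1.28 ± 0.07, HSF3 (Os09g0526600) at -1.20 ± 0.07 and RHSF2 (Os08g0546800) at -0.71 ± 0.05.

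Cytosolic ribosomal proteins stood higher in rss1 without salt: 53 of 155 rose, 4 fell and 98 did not pass (93 up and 4 down adjusted over the list alone). Their median was 0.21 (camera adjusted p = 1.31e-20, adjusted p = 0.430 with an estimated correlation). Of 96 class III peroxidases 11 rose and 2 fell (15 and 2 adjusted over the list alone). The median was 0.17 (adjusted p = 0.00777, adjusted p = 0.367 with an estimated correlation). Mitosis genes fell in 6 of 65 cases and rose in 0, also adjusted over the list alone. Their median was -0.11 (adjusted p = 0.000515, adjusted p = 0.545 with an estimated correlation). Core histones fell in 2 of 47 cases (0 adjusted over the list alone). The median was -0.11 (adjusted p = 0.00947, adjusted p = 0.651 with an estimated correlation). DNA replication genes fell in 2 of 33 cases (7 down and 1 up adjusted over the list alone). Their median was -0.12 (adjusted p = 0.0121, adjusted p = 0.593 with an estimated correlation). Without rss1 control replicate 2 and without replicate 2, the histone call ended (0.136 and 0.191; 1.4e-08 to 0.224 over the alternatives), as did that of DNA replication (0.195 and 0.234; 0.00161 to 0.234). The histone call also ended with the scanner log ratio (0.0603), median centring (0.0765) and Cy3 alone (0.224, and 0.158 with the replicate block), and that of DNA replication with the outlying background spots kept (0.0561). Of 94 antioxidant enzymes 7 rose and 6 fell (9 and 7 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.0293, adjusted p = 0.450 with an estimated correlation), a call that ended without WT control replicate 2 (0.0527), rss1 control replicate 2 (0.190) and replicate 2 (0.301; 0.0022 to 0.301 over the alternatives).

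Calls of single genes rested on few arrays in this comparison. The nicotianamine synthase Os03g0307200 rose by 4.10 ± 0.58 (adjusted p = 0.00261, WT control measured on 1 of 3 arrays), and its adjusted p was 0.0663 without replicate 1 and 0.0517 without replicate 2 (8.82e-05 to 0.0663 over the alternatives). The auxin efflux carrier Os06g0660200 rose by 2.01 ± 0.25 (0.00147), with 0.0847 without replicate 1 (0.000322 to 0.0847), and the ribosomal protein S17-4 (Os03g0109500) by 0.59 ± 0.08 (0.00259), with 0.130 without replicate 1 (0.000879 to 0.130). Aquaporin PIP2.3 (Os09g0541000), measured on 2 of 3 rss1 control arrays, fell by 1.02 on the log2 scale (0.00685), and the call ended without replicate 1 (0.0822), without replicate 3 (0.0573) and with the outlying background spots kept (0.131; 0.00274 to 0.131 over the alternatives). Lipid transfer protein LTP1 (Os05g0477900) rose by 1.03 ± 0.08 and glutathione S-transferase 40 (Os07g0168300) by 0.86 ± 0.07. Of the well-known salt and meristem genes 0 of 17 rose and 3 fell (camera adjusted p = 0.954). RAB16B had 0.08 (0.677) and the ABA-responsive element binding factor 0.18 (0.108).

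In total 2448 genes passed, 1169 up and 1279 down, 246 of them by at least 1 in log2, and 2446 had the same sign on all 3 slides, while the split was 614 up and 1523 down with median centring. The count was 219 without replicate 1, 460 without replicate 2, 921, 900 and 964 without WT control replicates 1, 2 and 3, and 1306 without rss1 control replicate 1. It was 1332 with the outlying background spots kept and 9683 with the ratio tested against 0, without the WT control arrays. The count of 9683 can include the dye bias of each probe, which subtracting the self-hybridised arrays removes.

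Across genes, the change in rss1 without salt went with the WT response to salt (Pearson r = 0.46 over 24295 genes, which are not independent replicates). Both comparisons subtract the same WT control arrays, and simulated data with no effect gave at most r = 0.148. Of the genes that passed in both, 583 were higher in both, 707 were lower in both and 221 had opposite signs, counts that the shared arrays also affect.

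The effect of the mutation on salt was asked by comparing rss1 salt with WT salt. Among the largest rises, a subtilase protease (Os01g0795200) was at least 54.0-fold higher (adjusted p = 1.02e-07), glutathione S-transferase GST7 (Os01g0949900) rose by 4.92 ± 0.16 (3.91e-08), and non-symbiotic hemoglobin 1 (Os03g0233900), a protein of low-oxygen and nitric oxide metabolism, by 4.40 ± 0.40 (1.42e-05). A cytochrome P450 (Os11g0138300) was at least 16.8-fold higher and an aldo/keto reductase (Os04g0339400) at least 22.0-fold higher, while a flavin-containing monooxygenase (Os04g0223500) rose by 4.36 ± 0.31. Copper transporter 1 (Os01g0770700) had the largest fall named here, at -3.73 ± 0.22 (1.57e-06), followed by a cytochrome P450 (Os03g0138200) at -3.16 ± 0.54 and L-asparaginase (Os04g0650700), which releases nitrogen from asparagine, at -2.39 ± 0.35.

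**Figure D1:**
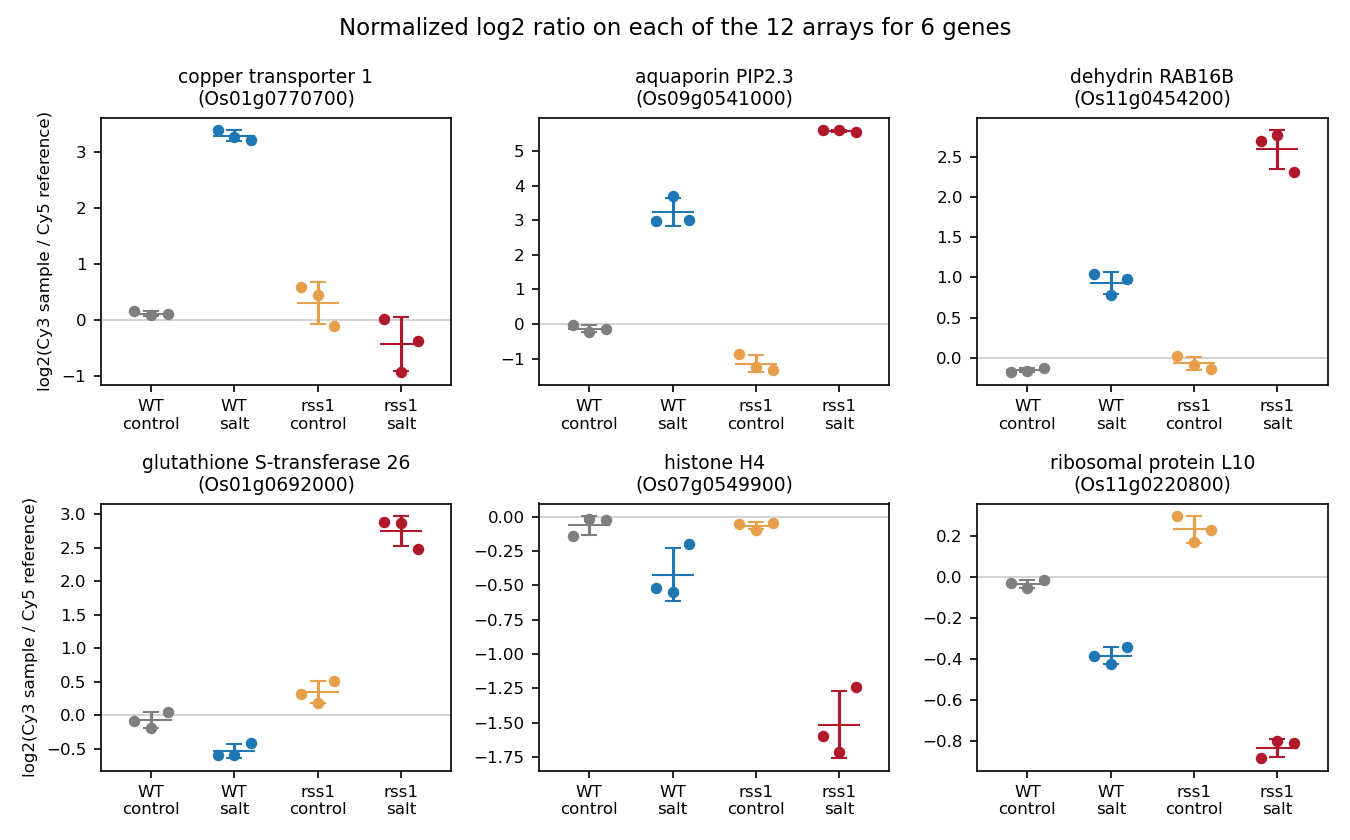
Normalized log2 ratio of the Cy3 sample to the Cy5 reference on each of the 12 arrays (points, 3 per group), with the group mean (bar) and SD (whiskers), for 6 genes. Copper transporter 1 averaged 3.30 in WT salt and -0.43 in rss1 salt, and aquaporin PIP2.3 3.24 and 5.59, whereas histone H4 averaged -0.42 and -1.52 and ribosomal protein L10 -0.38 and -0.83.

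Proliferation and translation lists were lower in rss1 than in WT on salt. Of 47 core histones 44 fell and 1 rose, also adjusted over the list alone. The median was -0.99 (camera adjusted p = 3.32e-10, adjusted p = 0.450 with an estimated correlation). Histone H3.2 (Os12g0415800) changed by -1.34 ± 0.14. DNA replication genes fell in 29 of 33 cases and rose in 1, also adjusted over the list alone. Their median was -0.70 (adjusted p = 6.73e-09, adjusted p = 0.434 with an estimated correlation). They included ORC1 (Os06g0187000), which marks replication origins, at -1.18 ± 0.09, and the DNA polymerase alpha catalytic subunit (Os01g0868300) at -0.94 ± 0.08. Of 65 mitosis genes 50 fell and 6 rose, also adjusted over the list alone, with a median of -0.60 (adjusted p = 9.70e-09, adjusted p = 0.444 with an estimated correlation), and cyclin A2 (Os12g0502300) fell by 1.00 on the log2 scale. G1 control genes fell in 8 of 13 cases and rose in 1, also adjusted over the list alone. The median was -0.27 (adjusted p = 0.0289, adjusted p = 0.367 with an estimated correlation). Among these were an E2F/DP factor (Os02g0739700) at -1.14 ± 0.12 and the retinoblastoma-related gene (Os08g0538700), whose product restrains E2F, at -0.96 ± 0.10. Of 155 cytosolic ribosomal proteins 145 fell and 2 rose (146 and 2 adjusted over the list alone), with a median of -0.42 (adjusted p = 3.54e-19, adjusted p = 0.434 with an estimated correlation), L44 (Os07g0523300) at -2.19 ± 0.06.

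Stress protection and defence lists were higher in rss1 than in WT on salt. Of 32 LEA proteins and dehydrins 25 rose and 1 fell (26 and 1 adjusted over the list alone). Their median was 0.84 (camera adjusted p = 1.57e-05, adjusted p = 0.188 with an estimated correlation). The LEA protein Os05g0542500 rose by 3.17 ± 0.32, and RAB16B by 1.66 ± 0.11 (adjusted p = 2.91e-06, and 0.0560 with the outlying background spots kept, with a range of 2.64e-07 to 0.0560). Antioxidant enzymes rose in 60 of 94 cases and fell in 13, also adjusted over the list alone, with a median of 0.56 (adjusted p = 3.24e-05, adjusted p = 0.290 with an estimated correlation), among them glutathione S-transferase 26 (Os01g0692000) by 3.28 ± 0.12. Of 156 defence genes 84 rose and 20 fell, also adjusted over the list alone, with a median of 0.63 (adjusted p = 0.000128, adjusted p = 0.290 with an estimated correlation), a beta-1,3-glucanase-like gene (Os08g0244500) by 2.32 ± 0.13. NAC, DREB and WRKY factors rose in 48 of 98 cases and fell in 14, also adjusted over the list alone, with a median of 0.38 (adjusted p = 0.00855, adjusted p = 0.450 with an estimated correlation), among them WRKY gene Os11g0116900 by 1.55 ± 0.11. Of 96 class III peroxidases 44 rose and 13 fell, also adjusted over the list alone. The median was 0.38 (adjusted p = 0.00947, adjusted p = 0.367 with an estimated correlation).

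Of 44 vascular and secondary wall genes 24 rose and 4 fell in the same comparison, also adjusted over the list alone. Their median was 0.56 (camera adjusted p = 0.000751, adjusted p = 0.290 with an estimated correlation). Cinnamoyl-CoA reductase (Os06g0623600), of lignin synthesis, rose by 1.36 ± 0.10. Cuticle and epidermis genes rose in 11 of 16 cases and fell in 3, also adjusted over the list alone. The median was 1.03 (adjusted p = 0.00777, adjusted p = 0.188 with an estimated correlation). Ion transport genes rose in 40 of 68 cases and fell in 9 (40 and 10 adjusted over the list alone). Their median was 0.24 (adjusted p = 0.00491, adjusted p = 0.188 with an estimated correlation). The SOS1-type sodium/proton exchanger Os12g0641100 rose by 0.59 ± 0.06 and NHX1 fell by 0.83 on the log2 scale (0.000568). Root and crown root markers rose in 7 of 14 cases and fell in 0 (6 and 0 adjusted over the list alone), with a median of 0.70 (adjusted p = 0.0201, adjusted p = 0.434 with an estimated correlation), RCc2 by 2.50 ± 0.22.

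Of 66 ABA pathway genes 34 rose and 14 fell in rss1 on salt (36 and 14 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.0289, adjusted p = 0.247 with an estimated correlation). That call ended without rss1 salt replicate 1 (0.0574), without replicate 1 (0.0549), with the scanner log ratio (0.0513), with every probe separately (0.0502) and in Cy3 alone (0.0888, and 0.0764 with the replicate block; 0.0129 to 0.0888 over the alternatives). The protein phosphatase 2C gene Os09g0325700, of a family that damps ABA signalling, rose by 2.34 ± 0.16, whereas the ABA synthesis gene NCED (Os03g0645900) fell by 0.52 on the log2 scale. Of the 17 well-known salt and meristem genes 11 rose and 3 fell, also adjusted over the list alone. Their median was 0.88 (adjusted p = 0.0394, adjusted p = 0.434 with an estimated correlation). Their call ended without rss1 salt replicate 1 (0.0756), without replicate 2 (0.0545), with offset 0 (0.0517), the strict filter (0.0839), every probe separately (0.0870) and the outlying background spots kept (0.0653), and in the deposited values (0.110; 0.0111 to 0.110 over the alternatives). The salt-induced lectin SALT (Os01g0348900) rose by 2.29 ± 0.26 and the NAC factor Os01g0884300 by 0.88 ± 0.15, while DREB1A (Os09g0522200) fell by 1.30 on the log2 scale (2.62e-05). Photosynthesis genes rose in 51 of 119 cases and fell in 27 (adjusted p = 0.0621, and 0.0489 with the replicate block; 0.000376 to 0.433 over the alternatives, 8 of which passed). Jasmonate genes rose in 13 of 34 cases and fell in 2 (0.0679; 0.0110 to 0.301, with 11 alternatives that passed).

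Of all genes, 15798 passed between rss1 and WT on salt, 7864 up and 7934 down, 2230 by at least 1 in log2 (1750 up and 480 down), and 15574 had the same sign on all 3 slides. The split was 6248 up and 9910 down with the scanner log ratio and 5555 and 9951 with median centring. For the ACC synthase family gene Os10g0390600, which rose by 1.00 ± 0.07, a second probe gave -0.54.

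The response of rss1 to salt was asked by comparing rss1 salt with rss1 control. Aquaporin PIP2.3 rose by 6.74 ± 0.18 (adjusted p = 7.21e-09, rss1 control measured on 2 of 3 arrays), a Bowman-Birk proteinase inhibitor (Os01g0123900) by 5.43 ± 0.35 (5.02e-07, also on 2 of 3) and an oxalate oxidase (Os08g0189200), a hydrogen peroxide source, by 4.82 ± 0.43 (3.47e-06). The LEA protein Os05g0542500 rose by 4.54 ± 0.32, raffinose synthase (Os07g0209100), which makes a protective sugar, by 3.76 ± 0.20, SALT by 3.50 ± 0.26 and RAB16B by 2.65 ± 0.11. Among the largest falls were nodulin 21 (Os04g0538400) at -3.03 ± 0.17, an ERF domain factor (Os09g0286600) at -2.79 ± 0.21 and growth-regulating factor 3 at -1.78 ± 0.12.

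Nearly every ribosomal protein was lower on salt in rss1: 152 of 155 fell and 1 rose (153 and 1 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 5.17e-29, adjusted p = 0.358 with an estimated correlation), and L10 (Os11g0220800) fell by 1.07 on the log2 scale. Core histones fell in 44 of 47 cases and rose in 1 (45 and 1 adjusted over the list alone), with a median of -1.25 (adjusted p = 6.92e-10, adjusted p = 0.450 with an estimated correlation), histone H4 (Os07g0549900) at -1.45 ± 0.12. Of 33 DNA replication genes 30 fell and 1 rose (31 and 1 adjusted over the list alone), with a median of -1.01 (adjusted p = 6.73e-09, adjusted p = 0.434 with an estimated correlation), the DNA polymerase delta small subunit (Os03g0128500) at -1.12 ± 0.06. Mitosis genes fell in 48 of 65 cases and rose in 8, also adjusted over the list alone, with a median of -0.65 (adjusted p = 1.21e-06, adjusted p = 0.450 with an estimated correlation), the B-type cyclin Os06g0726800 at -1.32 ± 0.07. Meristem and leaf primordium regulators fell in 17 of 38 cases and rose in 8 and did not pass as a list (0.0898), though they did without replicate 1 (0.0476) and with every probe separately (0.0334; 0.0334 to 0.25 over the alternatives).

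LEA proteins and dehydrins rose on salt in rss1 in 24 of 32 cases and fell in 2 (25 and 2 adjusted over the list alone). The median was 0.92 (camera adjusted p = 0.000262, adjusted p = 0.247 with an estimated correlation). Of 94 antioxidant enzymes 64 rose and 17 fell (65 and 17 adjusted over the list alone). Their median was 0.61 (adjusted p = 0.000161, adjusted p = 0.341 with an estimated correlation). Ion transport genes rose in 40 of 68 cases and fell in 9, also adjusted over the list alone, with a median of 0.43 (adjusted p = 0.000418, adjusted p = 0.188 with an estimated correlation), among them a plasma membrane proton ATPase (Os03g0689300) by 1.80 ± 0.11. Of 156 defence genes 79 rose and 25 fell, also adjusted over the list alone. The median was 0.76 (adjusted p = 0.00148, adjusted p = 0.367 with an estimated correlation). NAC, DREB and WRKY factors rose in 53 of 98 cases and fell in 15, also adjusted over the list alone. Their median was 0.49 (adjusted p = 0.0105, adjusted p = 0.450 with an estimated correlation). Of 34 jasmonate genes 20 rose and 3 fell, also adjusted over the list alone, with a median of 0.75 (adjusted p = 0.00649, adjusted p = 0.450 with an estimated correlation), lipoxygenase 1 (Os03g0700400) by 2.43 ± 0.10.

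Vascular and secondary wall genes rose on salt in rss1 in 30 of 44 cases and fell in 4, also adjusted over the list alone. The median was 0.71 (camera adjusted p = 0.000788, adjusted p = 0.290 with an estimated correlation). Of 16 cuticle and epidermis genes 12 rose and 3 fell, also adjusted over the list alone, with a median of 1.35 (adjusted p = 0.00649, adjusted p = 0.188 with an estimated correlation), LTP2P by 4.20 ± 0.16. Photosynthesis genes rose in 68 of 119 cases and fell in 23, also adjusted over the list alone. Their median was 0.43 (adjusted p = 0.00332, adjusted p = 0.529 with an estimated correlation). That call ended in the deposited values (0.0601; 3.82e-08 to 0.0601 over the alternatives). A Rubisco small subunit gene (Os12g0274700) rose by 2.07 ± 0.11. Root and crown root markers rose in 11 of 14 cases and fell in 0, also adjusted over the list alone, with a median of 0.90 (adjusted p = 0.0192, adjusted p = 0.434 with an estimated correlation), RCc2 by 3.76 ± 0.22. Of 66 ABA pathway genes 36 rose and 19 fell, also adjusted over the list alone, with a median of 0.24 (adjusted p = 0.0333, adjusted p = 0.247 with an estimated correlation), and the call ended without rss1 salt replicate 1 (0.0550), with the scanner log ratio (0.0683) and in Cy3 alone (0.0878, and 0.0781 with the replicate block; 0.0132 to 0.0878 over the alternatives). Class III peroxidases rose in 45 of 96 cases and fell in 16 (0.0846), and expansins and wall-loosening genes rose in 44 of 81 and fell in 20 (0.0643). Each of these lists passed under 8 alternatives, with ranges of 0.0170 to 0.147 and 0.00334 to 0.141.

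Several lists passed in none of the comparisons, though with every probe separately aquaporins passed in rss1 without salt (camera adjusted p = 0.00519), in rss1 on salt (0.0116) and in the interaction (0.0334), the lowest values over the alternatives, where the highest were 0.991, 0.609 and 0.718. Heat shock proteins in rss1 without salt had 0.0853, and passed without replicate 1 (0.00905), without rss1 control replicate 1 (0.0172) and with every probe separately (0.0159), with a range of 0.00905 to 0.301 over the alternatives. In WT and rss1 on salt, respectively, auxin genes rose in 38 and 56 of 113 cases and fell in 23 and 28 (camera adjusted p = 0.217 and 0.122), and heat shock proteins rose in 31 and 69 of 144 cases and fell in 22 and 41 (0.437 and 0.225). Cytokinin genes rose in 10 and 13 of 41 cases and fell in 11 and 14 (0.954 and 0.763), gibberellin genes rose in 6 each of 23 and fell in 7 and 8 (0.954 and 0.349), and ethylene genes rose in 6 and 7 of 19 and fell in 3 and 7 (0.178 and 0.617). Aquaporins rose in 7 and 8 of 17 cases and fell in 4 and 3 (0.537 and 0.230), and osmolyte synthesis genes rose in 6 and 7 of 20 cases and fell in 2 and 5 (0.287 and 0.791). Reference genes of expression studies rose in 11 and 17 of 39 cases and fell in 3 and 13 (0.408 and 0.760). The median of the aquaporins was -0.01 in WT where their mean was 0.28, and that of the reference genes -0.01 in rss1 where their mean was 0.15.

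In total 17744 genes passed in rss1 on salt, 9170 up and 8574 down, 3603 by at least 1 in log2 (2575 up and 1028 down), and 17570 had the same sign on all 3 slides. The split was 7292 up and 10622 down with the scanner log ratio and 6234 and 11208 with median centring.

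Whether the response to salt differed between genotypes was asked with the interaction, the salt change in rss1 minus that in WT. Ascorbate oxidase (Os06g0567900), a copper enzyme, had an interaction of 3.77 ± 0.17 (adjusted p = 3.70e-06) and the flavin-containing monooxygenase Os04g0223500 one of 3.78 ± 0.44 (0.000271). Those of aquaporin PIP2.3 (3.37 ± 0.25, on 2 rss1 control arrays), SALT (2.48 ± 0.37), the PP2C gene Os09g0325700 (2.41 ± 0.23), raffinose synthase (2.33 ± 0.28) and copper/zinc superoxide dismutase 2 (Os07g0665200; 2.10 ± 0.17, 7.65e-05) were also positive. The nicotianamine synthases rose with salt in WT and had negative interactions of -5.65 ± 1.20 (Os03g0307300, 0.00373) and -4.86 ± 0.82 (Os03g0307200, 0.00123), each measured on 1 of 3 WT control arrays. Without salt both were already higher in rss1 than in WT, by 4.02 (adjusted p = 0.0163, 0.0021 to 0.15 over the alternatives) and 4.10. Their interactions include this higher level and do not show how far rss1 and WT differ on salt. Copper transporter 1 had -3.93 ± 0.32 (6.92e-05), L-asparaginase -3.26 ± 0.50 and expansin EXPA21 -1.52 ± 0.13.

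The salt changes of ribosomal, histone, replication and mitosis genes were more negative in rss1. Of 155 cytosolic ribosomal proteins 148 had a negative interaction and 0 a positive one (150 and 0 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 9.77e-31, adjusted p = 0.341 with an estimated correlation), L10 at -0.72 ± 0.07. Core histones had 37 negative and 1 positive of 47 (39 and 1 adjusted over the list alone), with a median of -0.93 (adjusted p = 9.18e-09, adjusted p = 0.450 with an estimated correlation), histone H4 at -1.09 ± 0.17. DNA replication genes had 27 negative and 1 positive of 33 (28 and 1 adjusted over the list alone), with a median of -0.66 (adjusted p = 1.84e-08, adjusted p = 0.434 with an estimated correlation), the replication helicase factor CDC45 (Os11g0128400) at -1.02 ± 0.15. Mitosis genes had 38 negative and 6 positive of 65 (43 and 7 adjusted over the list alone), with a median of -0.50 (adjusted p = 9.70e-07, adjusted p = 0.450 with an estimated correlation), the B-type cyclin Os06g0726800 at -0.81 ± 0.10. Meristem and leaf primordium regulators, lower on salt in WT, had 7 positive and 10 negative of 38 and did not pass (0.954).

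**Figure D2:**
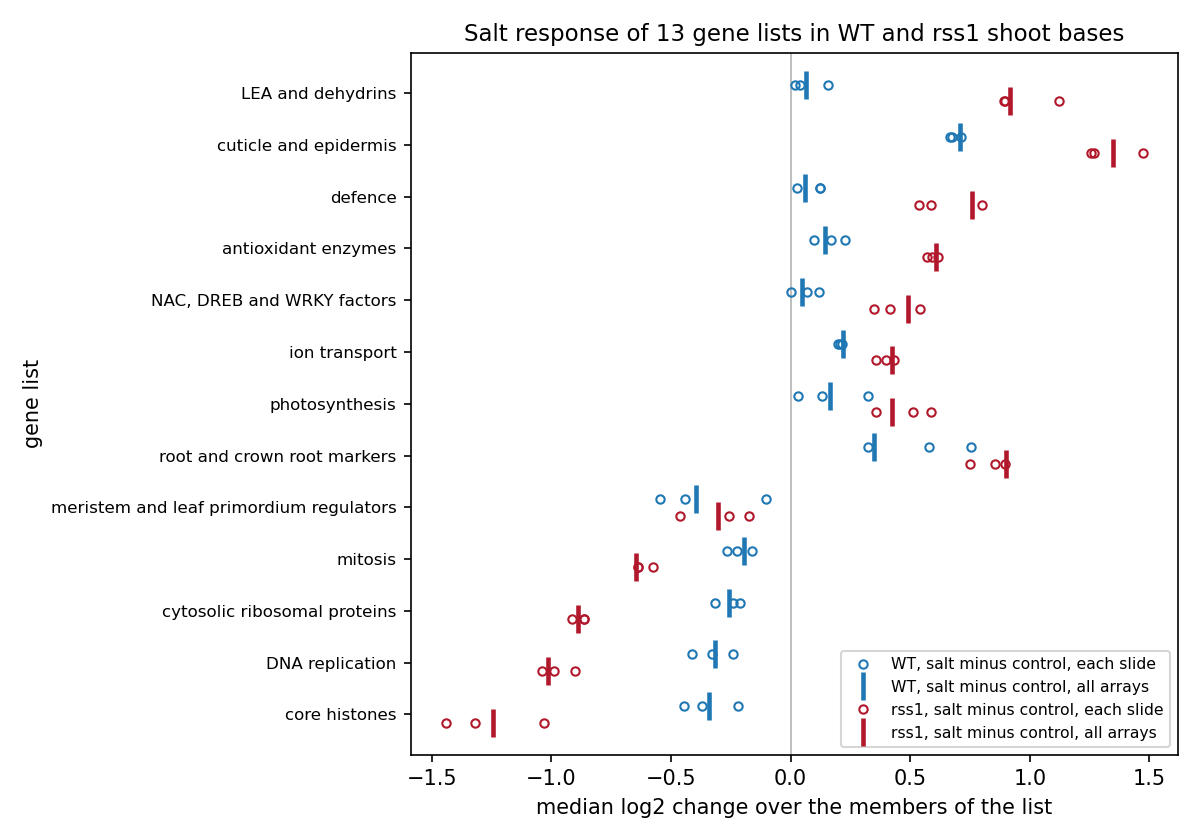
Median log2 change on salt over the members of 13 gene lists in WT and in rss1, on each of the 3 slides (open circles) and over all arrays (vertical marks). The medians of core histones were -0.34 in WT and -1.25 in rss1 and those of LEA proteins and dehydrins 0.07 and 0.92, and with median centring the WT medians of photosynthesis, LEA proteins and dehydrins, defence, and NAC, DREB and WRKY factors turned to -0.03, -0.09, -0.06 and -0.06.

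Protective lists had more positive salt changes in rss1. Of 32 LEA proteins and dehydrins 20 had a positive interaction and 3 a negative one (23 and 3 adjusted over the list alone). The median was 0.85 (camera adjusted p = 5.33e-05, adjusted p = 0.231 with an estimated correlation). RAB16B had 1.57 ± 0.16 (adjusted p = 0.000158, and 0.235 with the outlying background spots kept; 7.76e-06 to 0.235 over the alternatives). Defence genes had 60 positive and 16 negative of 156, also adjusted over the list alone. Their median was 0.60 (adjusted p = 0.000835, adjusted p = 0.341 with an estimated correlation). Antioxidant enzymes had 42 positive and 13 negative of 94, also adjusted over the list alone. The median was 0.35 (adjusted p = 0.000993, adjusted p = 0.367 with an estimated correlation). Cuticle and epidermis genes had 9 positive and 2 negative of 16 (10 and 2 adjusted over the list alone). Their median was 0.95 (adjusted p = 0.00513, adjusted p = 0.188 with an estimated correlation). Vascular and secondary wall genes had 17 positive and 3 negative of 44, also adjusted over the list alone, with a median of 0.32 (adjusted p = 0.00697, adjusted p = 0.367 with an estimated correlation), laccase (Os05g0458500), which polymerises lignin, at 1.77 ± 0.26. NAC, DREB and WRKY factors had 40 positive and 12 negative of 98, also adjusted over the list alone. The median was 0.37 (adjusted p = 0.00800, adjusted p = 0.450 with an estimated correlation).

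ABA pathway genes had 31 positive and 12 negative interactions of 66 (32 and 12 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00973, adjusted p = 0.188 with an estimated correlation), and NCED had -0.70 ± 0.09. Ion transport genes had 25 positive and 6 negative of 68, also adjusted over the list alone, with a median of 0.24 (adjusted p = 0.0173, adjusted p = 0.239 with an estimated correlation), the SOS1-type exchanger at 0.66 ± 0.08, and this call ended with the outlying background spots kept (0.0653; 0.00752 to 0.0653 over the alternatives). Photosynthesis genes had 52 positive and 19 negative of 119 (53 and 21 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.0173, adjusted p = 0.569 with an estimated correlation), a call that ended without rss1 salt replicate 3 (0.0646), without replicate 3 (0.187), with median centring (0.0542), in Cy3 alone (0.0659) and in the deposited values (0.201; 1.26e-06 to 0.201 over the alternatives). The well-known salt and meristem genes had 9 positive and 3 negative of 17, also adjusted over the list alone. Their median was 0.72 (adjusted p = 0.0273, adjusted p = 0.434 with an estimated correlation). Their call ended without rss1 salt replicate 1 (0.0503), without replicate 2 (0.0740), with the strict filter (0.0627), with the outlying background spots kept (0.0653) and in the deposited values (0.0600; 0.0112 to 0.0740 over the alternatives). Root and crown root markers had 3 positive and 0 negative of 14 (0.120), and G1 control genes 1 and 8 of 13 (0.0767). The root markers passed without replicate 1 (0.0476), without rss1 control replicate 1 (0.0360) and with every probe separately (0.0253; 0.0253 to 0.204 over the alternatives), and G1 control genes with no filter (0.0478) and every probe separately (0.0362; 0.0362 to 0.0989).

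Across genes the salt changes of the genotypes correlated (Pearson r = 0.63, Spearman rho = 0.64 over 24295 genes; 0.508 to 0.628 between differences within a slide). They were higher in both for 4088 genes where independence gives 2058, lower in both for 4260 where it gives 1935, and of opposite sign for 738. For size, the 17501 genes that passed in the mean salt response of both genotypes were used. Their median change in the direction of that mean was 0.25 ± 0.03 in WT and 0.54 ± 0.02 in rss1 (SD over n = 3 slides, exact paired sign permutation p = 0.25, two-sided and the smallest that 3 slides allow). The direction was taken from the same arrays and is that of a gene's larger change, so this measure favours the genotype with larger changes. Over all genes the median absolute salt change was 0.20 in WT and 0.41 in rss1. The least-squares slope of the rss1 salt change on that of WT was 1.02. Such a slope falls with the correlation, here 0.63, so it does not show that the responses were equally large.

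The interaction passed for 11652 genes, 5881 positive and 5771 negative, 1729 by at least 1 in log2 (1323 and 406), and 11489 had the same sign on all 3 slides, while the scanner log ratio gave 4611 positive and 7138 negative. The count was 3097 without replicate 1, 7413 without replicate 2 and 7582 with the outlying background spots kept.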

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

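Of the tests in this part, those on root tissue, on copper-responsive regulation, on placement along chromosome 6 and on a DNA difference of that segment were written only after the results they examine had been seen, and the groups of copper genes and microRNAs and the chromosome 6 segment were also picked after seeing the data.

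The change in rss1 without salt went in the same direction as the WT response to salt across genes (r = 0.46), although the comparisons share the WT control arrays and the reference RNA. Pairs of arrays with different replicate numbers, which share neither, kept 90.6% of the covariance (mean 0.0588, from 0.022 to 0.0869, against 0.065 over all arrays), and simulated data with no effect gave at most 0.00226, so shared controls are unlikely to account for it. The Cy3 signal alone kept a mean correlation of 0.265 over 6 pairs of different numbers (0.148 to 0.379), against 0.327 in the ratios. Taking ratios to the reference channel is thus also unlikely to account for it. That Cy3 signal was already dye-normalized, so it cannot exclude an effect of dye normalization. More root tissue at the shoot base of both could raise shared genes, and the 5 root and crown root markers that rose in WT on salt had a median of 0.359 in rss1 without salt, where 0 of 14 markers passed. The 5 genes ran from -0.156 to 0.485 (SD 0.264), so a difference in tissue remains open.

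Most copper uptake genes rose on salt in WT and stood lower in rss1 on salt, together with precursors of microRNAs known to act on copper proteins. Of 5 copper uptake and chaperone genes 4 rose in WT and had negative interactions, among them copper transporter 1 (3.19, interaction -3.93) and the copper chaperone homolog Os02g0530100 (1.99 and -1.97), but the homolog Os08g0405700 fell by 0.75 on the log2 scale in WT and its interaction of 0.22 did not pass (camera adjusted p = 0.0140 in WT and 0.0101 for the interaction, adjusted p = 0.198 and 0.181 with an estimated correlation). The 8 probes of miR398, miR408 and miR528 all rose in WT (median 1.93, adjusted p = 1.16e-06, adjusted p = 0.181 with an estimated correlation) and all had negative interactions (median -2.41, adjusted p = 1.51e-06, adjusted p = 0.181 with an estimated correlation). In Cy3 alone 12 of 12 genes and probes kept their negative interaction, so taking ratios to the reference channel is unlikely to make this pattern. That signal was already dye-normalized, so it cannot exclude an effect of dye normalization. The 8 probes are repeated readings of the miR398b, miR408 and miR528 precursors, and 4 of them share sequence within a precursor. The 12 are therefore not separate measurements. Shared probe sequence is unlikely to make the pattern, since 0 pairs of different genes share one. If WT but not rss1 sensed a lack of copper, copper proteins might have a lower salt change in WT than in rss1, and the 45 such genes had a median interaction of 0.16 (19 positive and 9 negative, adjusted p = 0.0877, adjusted p = 0.440 with an estimated correlation), which came from rises in rss1 on salt (23 up and 10 down, median 0.38) and not from a fall in WT (13 up and 13 down, median 0.05, adjusted p = 0.999), so this explanation stays open.

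A run of neighbouring genes on chromosome 6 was lower in rss1 with and without salt. Of 17 genes measured between Os06g0175900 and Os06g0178600, 12 were lowered in both conditions, counting changes of -0.4 or below in log2. Their medians were -0.825 without salt and -0.875 with salt. Smaller falls in the segment were not counted. Cross-hybridisation is unlikely to make the run, since 6 of the lowered members share no probe sequence with another gene, and chance placement is unlikely, since 12 of the 144 genes lowered this far lay in a window of 20 where 10000 random orders gave at most 5 (permutation p = 1e-04, the smallest possible). A DNA difference of the segment in the mutant line would lower its genes alike in both conditions, and genes picked on the change without salt alone, in the window of 20 that holds most of them, were the same 12, of which 0 had an interaction that passed, against 69.9% of the 535 other genes lowered as far without salt (4 of 12 against 66.4% in Cy3 alone). This is in line with such a difference but leaves it open, since the Cy3 count is less clear, neighbours are not independent, 4 of the 5 other genes of the segment had an interaction that passed, genomic DNA was not analysed here, and the change of -0.4 and the window were set after seeing the run.

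Regrouping the arrays asked how many genes pass when the groups are mixed. With 10 splits of 6 arrays no share under 0.05 can be reached, and the real grouping gave the most genes in each comparison: 10935 against at most 0 otherwise for WT on salt, 2448 against 0 for rss1 without salt, 15798 against 2 for rss1 and WT on salt, and 17744 against 2 for rss1 on salt, 1 of 10 splits each. Every other split puts both conditions into each group, so a large difference between them widens the spread within groups. Low counts in the other splits follow from this and do not test the calls. For the interaction, only the real grouping among 100 groupings of all 12 arrays reached 11652 genes, and the highest other count was 10103. Shuffled groups still hold the effects of salt and genotype and ignore the slides, so this count does not test whether the salt responses differ. Lists passed less distinctly: 13 lists for WT on salt against at most 12 (1 of 10 splits), 6 for rss1 without salt against 9 (7 of 10), 16 for rss1 and WT on salt against 18 (2 of 10), 15 for rss1 on salt against 14 (1 of 10) and 14 for the interaction against 16 (20 of 100). Mixed groups still hold part of the real effects, so what the lists called in them rest on is left open.

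The salt change of 11652 genes differed between rss1 and WT. Single genes with large positive differences were the subtilase Os01g0795200 (5.39), non-symbiotic hemoglobin 2 (Os03g0226200, 4.42, with an adjusted p = 0.00373 that was 0.0770 without replicate 1 and ran from 0.000938 to 0.0770 over the alternatives), the cytochrome P450 Os11g0138300 (3.91) and the subtilase Os01g0795400 (3.79, with 0.00998 that was 0.0932 without replicate 1 and 0.0603 without replicate 2, from 0.000901 to 0.0932). The flavin-containing monooxygenase Os04g0223500 had 3.78, ascorbate oxidase (Os06g0567900) 3.77, the glucosyltransferase Os03g0757600 3.73 and GST7 (Os01g0949900) 3.62. The sizes of 4 of these, and so their order, are not defined, since Os01g0795200, Os11g0138300 and Os03g0757600 were well above background on 1 of 3 WT control and 0 of 3 WT salt arrays and GST7 on 0 of 3 WT control arrays. Large negative differences included those of the nicotianamine synthases Os03g0307300 (-5.65) and Os03g0307200 (-4.86). Each was measured on 1 of 3 WT control arrays, so these sizes are uncertain. Without salt both were already higher in rss1 than in WT, by 4.02 and 4.10, which enters these large negative differences. Others were those of a second beta-glucosidase aggregating factor (Os12g0198700, -4.43, adjusted p = 0.0125, 0.0539 without replicate 1 and 0.0513 without replicate 2, from 0.00569 to 0.0539) and the von Willebrand factor type A domain gene Os11g0687100 (-4.18, 0.00914, 0.0656 without replicate 2 and 0.0565 without replicate 3, from 0.00305 to 0.0656). Copper transporter 1 (Os01g0770700) had -3.93, L-asparaginase (Os04g0650700) -3.26, lipoxygenase L-2 (Os03g0738600) -3.08 (measured on 2 of 3 WT control arrays, adjusted p = 0.00545, 0.0899 without replicate 1, from 0.00125 to 0.0899) and the Bet v I family gene Os08g0374000 -2.76 (0.0179, 0.101 without replicate 1 and 0.0954 without replicate 2, from 0.0017 to 0.101). Lipoxygenase L-2 had a change of 2.38 in rss1 without salt (adjusted p = 0.0157, from 0.0029 to 0.233), which enters its difference.

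The lists whose salt change was lower in rss1 than in WT were core histones (median difference -0.93), DNA replication (-0.66), cytosolic ribosomal proteins (-0.64) and mitosis (-0.50), and none of these kept its call with an estimated correlation (adjusted p = 0.450, 0.434, 0.341 and 0.450). Those with a higher salt change were cuticle and epidermis genes (0.95), LEA proteins and dehydrins (0.85), the well-known salt and meristem genes (0.72) and defence genes (0.60), where the same test gave adjusted p = 0.188, 0.231, 0.434 and 0.341. Smaller differences were those of NAC, DREB and WRKY factors (0.37), antioxidant enzymes (0.35), photosynthesis (0.34) and vascular and secondary wall genes (0.32), with adjusted p = 0.450, 0.367, 0.569 and 0.367. ABA pathway genes had 0.25 and ion transport genes 0.24, with adjusted p = 0.188 and 0.239.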

How the results depend on the processing

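All settings here were fixed in advance, except that removing the outlying background spots, as in the values reported, and keeping them, as an alternative, were both chosen after seeing the data. A minimum absolute log2 change of 1 left 1077, 246, 2230, 3603 and 1729 genes for WT on salt, rss1 without salt, rss1 against WT on salt, rss1 on salt and the interaction.

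Testing the ratio against 0, without the WT control arrays, gave 9683 genes for rss1 without salt, a count that can include the dye bias of each probe. With the outlying background spots kept, 1332 genes passed in rss1 without salt and 7582 in the interaction. The 6 spots lie on rss1 salt arrays, which are not compared in rss1 without salt. The count there thus changed through the variance pooled over all arrays. In the interaction the values also changed, as the spots enter the background correction and normalization of their whole arrays. The interaction of RAB16B, for example, was 1.57 without these spots and 0.92 with them. Of 624 calls of named genes 560 remained with the outlying background spots kept. For Os10g0390600 a second probe had the opposite sign in rss1 against WT on salt (-0.54), in rss1 on salt (-0.49) and in the interaction (-0.55).

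Leaving out single arrays or replicates, the counts ran from 5270 (without replicate 1) to 10207 (without replicate 3) for WT on salt, from 219 (without replicate 1) to 2795 (without replicate 3) for rss1 without salt, from 10652 to 16518 for rss1 against WT on salt, from 14112 to 18082 for rss1 on salt and from 3097 (without replicate 1) to 13384 (without rss1 salt replicate 3) for the interaction. In rss1 without salt, leaving out replicate 1 or 2 ended the calls of 76 and 65 of the 99 named genes.

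The list tests passed 0 with an estimated correlation and 107 with fry, against 64. The replicate block gained the list call of photosynthesis in rss1 against WT on salt. Among named genes it lost the calls of Os01g0959100 and Os03g0674700 in rss1 without salt and gained 13.

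The slope of the rss1 on the WT change was 1.02, which also depends on their correlation and does not compare their sizes. The median signed change on salt, over the genes that passed in the mean salt response, was larger in rss1 by 0.30. This difference was 0.368 with the scanner log ratio, 0.366 in Cy3 alone and 0.233 with the outlying background spots kept, and 0.313 to 0.359 without replicate 1 or replicate 2. The correlation of the salt responses ran from 0.580 to 0.675 when arrays were left out.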

Other observations

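The groups of genes in this part were picked only after their members had been seen among the largest changes, so their tests describe these data and carry the choice with them.

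Precursor probes of miR395, a microRNA known to rise when sulfate is short, were called neither in WT on salt nor in rss1 without salt (0 of 22), while 22 of 22 were higher in rss1 than in WT on salt (median 1.38, camera adjusted p = 2.53e-06, adjusted p = 0.361 with an estimated correlation). The slide medians were 1.48, 1.91 and 0.71, and the probe osa-miR395m 3'seq had -0.01 on slide 3. In rss1 on salt 22 of 22 rose (median 1.42, adjusted p = 3.90e-05, adjusted p = 0.424 with an estimated correlation), and 20 had a positive interaction (median 1.44, adjusted p = 2.51e-06, adjusted p = 0.361 with an estimated correlation). In Cy3 alone the medians of these comparisons were several-fold larger, at 4.40, 4.49 and 4.93, so the sizes depend on the processing. Cy3 alone differs from the ratios in the background correction, without the normexp offset, as well as in the channel. Which of these made the difference was not tested. Of these probes 16 share sequence with another, so they are not separate measurements.

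Of 5 genes described with the word hemoglobin, 4 of them hemoglobins and 1 a ferric leghemoglobin reductase, all were higher in rss1 than in WT on salt, with a median of 3.25 (camera adjusted p = 0.0101, adjusted p = 0.322 with an estimated correlation). That median comes from the 3 non-symbiotic hemoglobins, as the reductase Os01g0328700 had 0.35 and the 2-on-2 hemoglobin Os06g0591600 0.22, and neither passed in Cy3 alone (0.16, adjusted p = 0.0894, and 0.09, adjusted p = 0.350). Of 15 metallothioneins, small metal-binding proteins, 6 rose in the same comparison with a median of 1.31 over the list (adjusted p = 0.0243, adjusted p = 0.273 with an estimated correlation). Of 50 glutathione S-transferases 33 rose and 8 fell, with a median of 0.58 (adjusted p = 0.00148, adjusted p = 0.181 with an estimated correlation).

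Genes described with the word nitrate, which are nitrate transporters, nitrate reductases and 5 nitrate-induced NOI family genes, rose on salt in 14 of 15 cases in rss1, with a median of 0.81 (camera adjusted p = 0.00294, adjusted p = 0.181 with an estimated correlation), and in 7 of 15 in WT, with a median of 0.43 (adjusted p = 0.00393, adjusted p = 0.181 with an estimated correlation). The interaction was positive in 7 of 15 and negative in 0, with a median of 0.30 (camera adjusted p = 0.0453, adjusted p = 0.272 with an estimated correlation). Of 10 proteinase inhibitors, which hinder insect digestion, 9 rose and 1 fell on salt in WT with a median of 1.21 (adjusted p = 0.00422, adjusted p = 0.181 with an estimated correlation), and 8 rose in rss1 with a median of 2.39 (adjusted p = 0.00321, adjusted p = 0.181 with an estimated correlation).

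The gene Os02g0606700, described only as a conserved hypothetical protein, fell in rss1 by 2.50 on the log2 scale without salt (adjusted p = 9.08e-05) and by 2.87 on the log2 scale with salt (4.33e-06). Its interaction was -0.37 (adjusted p = 0.329).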
